A study of Haematococcus lacustris with 4 samples.

How the data were processed

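RNA sequencing was carried out on 4 samples of the green microalga Haematococcus lacustris, strain CCAP 34/8, 2 from cultures fed 2 mM nitrate and 2 from cultures fed 15 mM nitrate. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, the alga was grown in continuously fed illuminated columns and libraries were made from total RNA with a total RNA library kit, while the molecule is labelled as polyA RNA. No label says whether the replicates of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

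One table with a row per gene and a column per library was used. Its unit is not stated in the labels. The deposited values were treated as FPKM (fragments per kilobase of gene and per total of mapped fragments) because they carried up to 6 decimals, were never negative, and summed to different totals in the 4 libraries. These traits do not settle the unit. Per the submitters' processing notes, the tools FastQC, HISAT2, StringTie and limma were used. Their versions, their settings, the strand handling, the genome build and the gene annotation are not given in the sources used here. The table held 13248 genes, each above 0 in at least 1 library. If the values are FPKM, they are already divided by the number of mapped fragments and do not give the sequencing depth of each library. That depth is unknown, and no interval or detection floor that needs it is given. Among the 681 genes above 0 and under 5 FPKM in both 15 mM libraries, the commonest ratio between them (in bins 0.001 wide) was shared by only 5 genes. No read step was found in this way, so read counts were not recovered and no count model was fitted.

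A total of 25 deposited FPKM values, spread over all 4 libraries, were whole numbers above 0. They were about 1000 times the other replicate of their group where that replicate was above 0, with a median ratio of 980 over 23 values. No value in the table had exactly 3 decimals, although 278 had exactly 4. Test results were computed on the values as deposited. Library totals, levels, ratios between replicates and correlations are given after dividing these 25 values by 1000, and the effect of the division on the tests was computed as an alternative.

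Gene identifiers were matched against a gene table of another assembly of the species, and 0 of the 13248 identifiers matched. The deposited table does not pair identifiers with gene names. The 17 gene lists fixed before the data were examined (carotenoid synthesis, nitrogen assimilation, photosynthesis, flagella and others) were therefore not tested, and no gene product, position or pathway is given. The rule for naming genes, also fixed before the data were examined, takes in this case the 2 identifiers with the largest positive and the 2 with the largest negative log2 fold change. They had to have an adjusted p under 0.05, groups that did not overlap and a mean of at least 5 FPKM in the higher group.

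The comparison of 2 mM with 15 mM nitrate was made with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), a pseudocount of 1. Genes with a mean of at least 1 FPKM over the 4 libraries were kept, and lmFit and eBayes with an intensity trend were applied with no further normalization. Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Fold changes are on the log2(FPKM + 1) scale as 2 mM minus 15 mM, which understates the change of low genes. No fold is given where a group is listed at 0 throughout. The numbers of genes above 0 per library were compared with an exact permutation test in SciPy 1.17.1.

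The procedure was tested on simulated data with 11540 genes, levels taken from the 15 mM libraries and replicate spread taken from the same libraries by level, with 200 genes changed. It called 0% of the 2-fold, 2% of the 4-fold, 20% of the 8-fold and 38% of the 16-fold changes, 50 genes each, and 0 of the 11340 unchanged genes. Both groups had the levels and spread of the 15 mM libraries, without the extra zeros at 2 mM. The 0 calls among unchanged genes therefore do not carry over to the data. Each simulated gene was given the pooled spread of its level group, which includes genes at 0 in 1 of the 15 mM libraries. These shares therefore do not set the smallest change that could be called in the data. There 461 genes were called higher, of which 412 changed by at least 2-fold. A further simulation left the mean of all genes unchanged and set values of the 2 mM libraries to 0 at random. The 2 mM values kept were raised, being divided by the share kept at their level. All libraries were given the replicate spread of the 15 mM libraries, although the 2 mM replicates differed more. The SD of the log2 ratio between replicates, over genes above 0 in all 4 libraries, was 0.83 at 2 mM and 0.44 at 15 mM. The calls of this simulation are given in the results and with the closing observations. Alternatives planned before the data were examined were another pseudocount, other filters, quantile normalization, median centring, no intensity trend, a fold filter, the replicate number as a block, and leaving out each library. Alternatives added after the data were seen were the division of the whole values by 1000, tests restricted to genes above 0 in all 4 libraries or to a mean of at least 100 FPKM, and centring on the genes above 0 in all 4 libraries.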

Results

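Gene expression was measured by RNA sequencing in Haematococcus lacustris (also called Haematococcus pluvialis), a unicellular green alga that accumulates the red ketocarotenoid astaxanthin. The study, by its title, concerns macrozoids and palmelloid cells, which are motile and non-motile cell forms of the alga, in relation to astaxanthin accumulation. The 4 libraries are labelled only by the nitrate in the feed of the continuous cultures, 2 at 2 mM and 2 at 15 mM, and the labels do not say which cell form each library held. The comparison implied by the design is therefore 2 mM against 15 mM nitrate. Genes are given by the identifiers of the deposited table, without product or position.

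The libraries differed first in how many of the 13248 genes of the table were above 0. At 2 mM nitrate, 3262 genes were above 0 in replicate 1 and 3435 in replicate 2. At 15 mM nitrate, 11658 genes were above 0 in replicate 1 and 10794 in replicate 2. The means were 3348.5 ± 122 genes (SD, n = 2) at 2 mM and 11226 ± 611 genes (SD, n = 2) at 15 mM, a ratio of 3.35. The exact two-sided permutation test gave p = 0.333, the smallest value that 2 against 2 libraries allow. The summed FPKM of the libraries lay closer together, at 1293713 and 1310747 at 2 mM and at 1483953 and 1498832 at 15 mM, after 25 whole-number values had been divided by 1000. The sums as deposited were 1677309, 2693738, 40920464 and 2416808 in the same order. The median level of the genes above 0 was 113 and 106 FPKM at 2 mM and 18.2 and 21.7 FPKM at 15 mM.

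**Figure D1:**
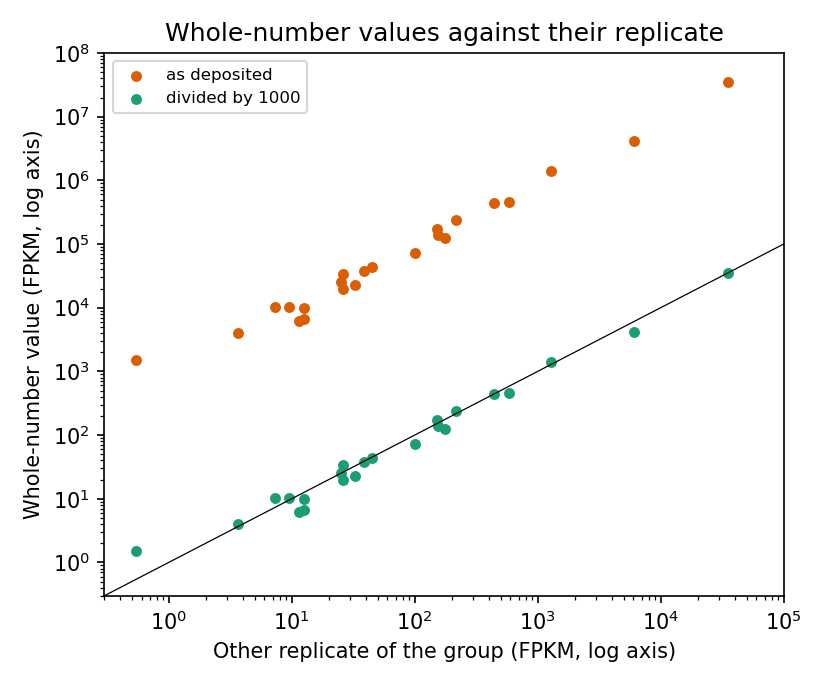
The 23 whole-number values whose other replicate was above 0 (vertical, FPKM, log axis) against that replicate (horizontal, FPKM, log axis), as deposited (orange) and divided by 1000 (green), with the line of equal values. The median ratio to the replicate is 980 as deposited and 0.980 after the division.

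The genes fell into groups by the libraries that listed them. The group above 0 in all 4 libraries held 2148 genes (16.2% of the table), with a median level of 175 FPKM at 2 mM and 120 FPKM at 15 mM. The group above 0 in both 15 mM libraries and at 0 in both 2 mM libraries was the largest, with 5596 genes (42.2%) and a median level of 15.2 FPKM at 15 mM. A further 3231 genes were above 0 in a single 15 mM library and at 0 in both 2 mM libraries. The opposite group, above 0 in both 2 mM libraries and at 0 in both 15 mM libraries, held 56 genes, with a median level of 161 FPKM at 2 mM. The genes that were abundant in one condition were mostly abundant in the other: 68 of the 100 genes with the highest mean at 2 mM were also among the 100 highest at 15 mM, against 0.755 expected by chance. Those 100 highest genes were taken without regard to replicate error. The chance value takes ranks as unrelated between libraries of the same alga, so exceeding it says little about nitrate. The 100 highest genes of each library held 39.2% and 38.2% of its summed FPKM at 2 mM and 42.1% and 44.3% at 15 mM.

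Whether a gene was above 0 at 2 mM followed its level at 15 mM. The genes compared here were those above 0 in both 15 mM libraries, by their mean there. Of the 2393 such genes at 20 to 50 FPKM at 15 mM, 26.2% were above 0 in replicate 1 at 2 mM and 28.7% in replicate 2. Of the 226 genes at 1000 FPKM or more, 95.6% were above 0 in each. The replicates at 2 mM also missed genes of each other: of the 549 genes at 20 to 50 FPKM in replicate 1, 45.9% were above 0 in replicate 2, against 92.4% of 2494 such genes between the 15 mM replicates. A gene at 0 in the 2 mM libraries is therefore described here only as listed at 0.

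**Figure D2:**
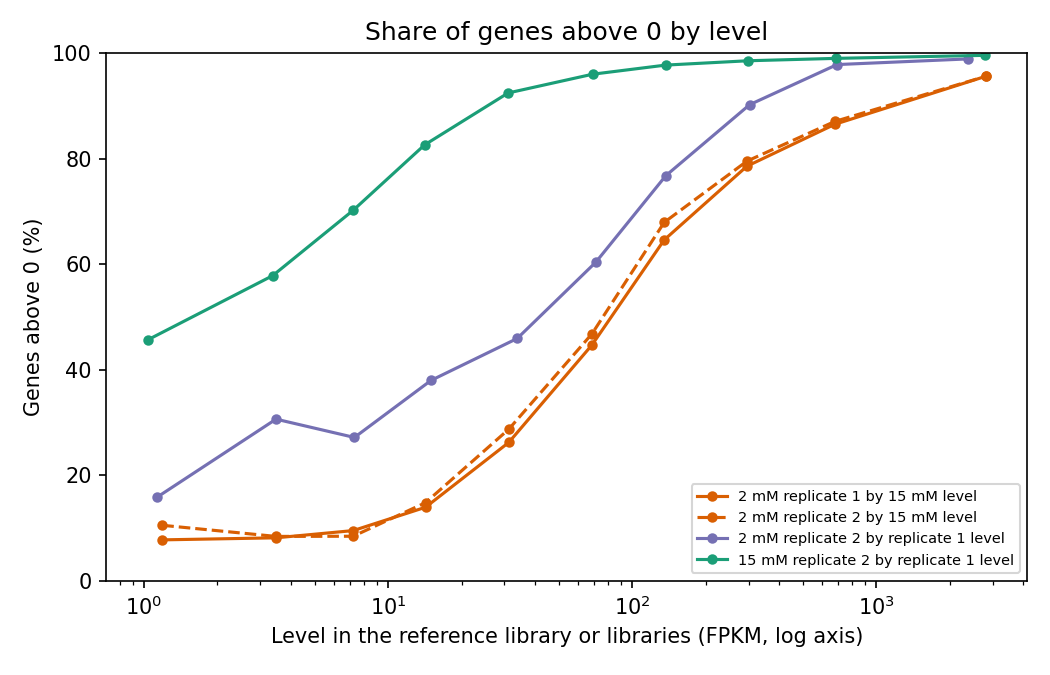
Percent of genes above 0 in one library (vertical axis) by the level in FPKM (log axis) in the reference. For the orange lines the reference is the mean of both 15 mM libraries, and only genes above 0 in both are used. For the purple (2 mM) and green (15 mM) lines it is the other replicate. Each point is a bin of level, and the share at 20 to 50 FPKM is 26.2% and 28.7% on the orange lines, 45.9% on the purple and 92.4% on the green.

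Of the 11816 genes tested with limma, 461 were called higher and 5307 lower at 2 mM nitrate at an adjusted p under 0.05. At an unadjusted p under 0.05 these counts were 624 and 5552. Of the genes called lower, 5150 (97.0%) were listed at 0 in both 2 mM libraries, 24 were above 0 in 1 of them and 133 were above 0 in all 4 libraries. The zeros of these 5150 genes have no spread, so their p-values do not measure variation between the 2 mM libraries. Of the genes called higher, 376 were above 0 in all 4 libraries, 30 were at 0 in 1 of the 15 mM libraries and 55 were at 0 in both. The lower calls made up 92.0% of all calls, and this split depended on the scaling: it was 67.1% after quantile normalization, 28.3% after centring each library on its median, and 95.1% (293 higher, 5631 lower) after centring on the genes above 0 in all 4 libraries. The median log2 fold change of all tested genes was -2.42 as deposited, 0.24 after quantile normalization, 1.83 after median centring and -2.97 after centring on the genes above 0 in all 4 libraries, and the calls as deposited were not made relative to that shift. Quantile normalization and median centring both act on the many zeros at 2 mM, so neither is a neutral scaling here. In 20 simulations of 11540 unchanged genes, set to 0 at 2 mM at the rates seen between the 2 mM replicates, limma called on average 1818.9 genes lower and 4.5 higher, against 5307 and 399 called among the same genes in the data. In these simulations 4317.1 genes were at 0 in both 2 mM libraries, against 7434 observed. The rates came only from genes already above 0 in the other 2 mM library, and zeros were drawn independently. The gap therefore does not measure what random loss leaves unexplained. With zeros set at the rates observed by 15 mM level, which include any real decreases, these counts were 4243 lower, 12.2 higher and 6803.1 at 0 in both. The count of higher calls also changed when 1 library was left out. It rose without either of the 2 mM libraries and fell without either of the 15 mM libraries. In such runs the spread of a gene comes from the other group alone, and the 2 mM replicates differed more. These shifts therefore cannot tell whether a single library set the count.

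The genes named by the fixed rule were each listed at 0 in one condition. HaLaN_24436 stood at 11082.2 and 14648.5 FPKM in the 2 mM libraries and was listed at 0 in both 15 mM libraries. HaLaN_22481 stood at 4715.24 and 5359.26 FPKM at 2 mM and was listed at 0 in both 15 mM libraries. HaLaN_29182 stood at 6646.07 and 5013.97 FPKM at 15 mM and was listed at 0 in both 2 mM libraries. HaLaN_10625 stood at 4864.58 and 4674.25 FPKM at 15 mM and was listed at 0 in both 2 mM libraries. The limma adjusted p was 0.000583 for each of these 4 genes, and their direction held under every alternative run in which they were tested. Each gene had an SD of 0 in the condition where it was listed at 0, so this p does not measure replicate spread there.

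The balance of the calls changed with the mean of the genes over the 4 libraries, which itself includes the zeros at 2 mM. Values above 0 and under 10 FPKM numbered 157 and 145 in the 2 mM libraries and 4028 and 3117 in the 15 mM libraries. A gene with a low mean therefore had little room to be called higher at 2 mM, and the low bins are not a result about expression level. Among the 5423 tested genes with a mean under 10 FPKM over the 4 libraries, 2919 were called lower, of which 2909 were listed at 0 in both 2 mM libraries, and 1 was called higher. Among the 1258 genes at 100 to 500 FPKM, 194 were called higher and 128 lower, and 97 of the lower ones were listed at 0 in both 2 mM libraries. Between these levels, 67 were called higher and 1969 lower at 10 to 50 FPKM, and 71 higher and 192 lower at 50 to 100 FPKM. Among the 213 genes at 500 to 1000 FPKM, 65 were called higher and 30 lower. Among the 252 genes at 1000 FPKM or more, 63 were called higher and 69 lower, and 65 of the lower ones were above 0 in both 2 mM libraries. The median log2 fold change of these most abundant genes was -0.03.

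The 2148 genes above 0 in all 4 libraries were tested among themselves, a restriction chosen after the data were seen. Of these, 445 were called higher at 2 mM, 391 of them by at least 2-fold, and 151 were called lower, 115 of them by at least 2-fold (limma, adjusted p under 0.05). After the whole-number values had been divided by 1000 the counts were 478 and 162. The median log2 fold change was 0.34, with 5% of the genes below -1.27 and 5% above 3.05. The SD across genes of the log2 ratio between replicates was 0.83 at 2 mM and 0.44 at 15 mM. Pearson's r of log2 FPKM across these genes was 0.92 between the 2 mM replicates, 0.98 between the 15 mM replicates, and 0.77 to 0.79 between libraries of different conditions. Genes are not independent replicates, and the restriction keeps genes whose 2 mM values were high enough to be listed.

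**Figure D3:**
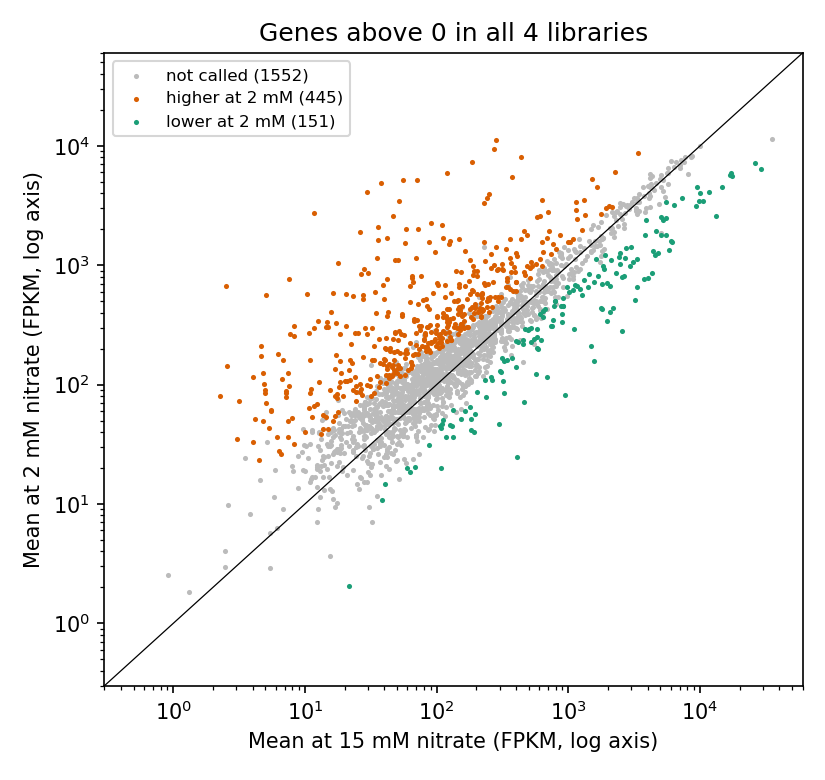
Mean FPKM at 2 mM (vertical, log axis) against mean FPKM at 15 mM nitrate (horizontal, log axis) of the 2148 genes above 0 in all 4 libraries, with 2 libraries per mean, whole-number values divided by 1000 and the diagonal marking equal levels. The 445 genes called higher at 2 mM (orange) and the 151 called lower (green) are from limma on the deposited values, and the other 1552 genes are grey.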

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

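The counts depended on the scaling and on which genes were tested. The count of genes higher at 2 mM was 461 as reported, 3382 after median centring of each library, 255 with the replicate block and 293 after centring on the genes above 0 in all 4 libraries, and ranged from 225 to 844 when 1 library was left out. The count of genes lower at 2 mM was 5307 as reported, 1158 after quantile normalization and 1333 after median centring. It was 151 when only genes above 0 in all 4 libraries were tested and 228 with a mean of at least 100 FPKM (fewer genes tested), and ranged from 5131 to 6547 when 1 library was left out. With a mean of at least 100 FPKM, 313 genes were higher, and 106 of the 228 lower ones were at 0 in both 2 mM libraries. Under median centring, 3053 genes were called in both that setting and the reported one, and 1259 of these changed sign, because the median of both 2 mM libraries lies at genes listed at 0. Quantile normalization gave the tied zeros of each 2 mM library a shared value above 0, so its counts also depend on those zeros. The other alternatives for these counts (pseudocount 0.1, the other filters, no intensity trend, at least 2-fold, whole values divided by 1000) stayed within 1.5 times the reported counts, with 397 to 484 genes higher and 3816 to 5544 lower. The 4 named genes kept their direction in every alternative in which they were tested. They were picked from these data for the largest changes and were each listed at 0 in one condition, so this says little about other genes. The replicate numbers are shared by both groups, but same-numbered libraries did not deviate together (correlation of deviations -0.002 across tested genes), so the replicate block pairs the samples by number only. With the block, 4643 genes were lower. Both restrictions of the genes, the centring on them and the division by 1000 were chosen after seeing the data. When 1 library is left out, the lone sample of its group is assumed to vary like the other group. The alternatives planned for the gene lists were not run, because no identifier could be paired with a name. The depth of the libraries is unknown, so their detection limits are too.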

Other observations

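The tests below were chosen after the results were seen.

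The first pattern is the genes listed at 15 mM nitrate and at 0 in both 2 mM libraries, and a candidate explanation for its low-level members is lower depth at 2 mM: of the genes under 50 FPKM in one 2 mM library, 61.1% were at 0 in the other, against 20.8% between the 15 mM libraries. In a simulation, 11540 genes, which include all 5307 called lower, were left unchanged and set to 0 at the rates seen between the 2 mM replicates. There limma called 1818.9 lower on average (at most 2076 in 20 simulations), with 4317.1 genes at 0 in both 2 mM libraries against 7434 observed. The rates between replicates came only from genes already above 0 in the other 2 mM library, and zeros were drawn independently. The gap therefore cannot tell how many of the zeros lower depth made. Rates taken by the 15 mM level gave 4243 lower calls and 6803.1 genes at 0 in both, but those rates contain the observed zeros, real decreases included, so that run bears on how limma treats zeros and not on what made them. For the abundant members the values argue against depth as the whole cause. Of 411 genes above 0 in both 15 mM libraries with a mean there of at least 500 FPKM, 29 were at 0 in both 2 mM libraries. A further 11 were at 0 in 1 of them. Random loss, independent in each library, would leave more genes missed once than in both, except among very short genes, which were not tested. Loss shared by both 2 mM libraries is not covered by this comparison and was not tested. The 302 values above 0 and under 10 FPKM argue against a lower limit on level at 2 mM. A response to nitrate, a different cell form and reads placed differently between near-identical gene copies stay open for low-level and abundant members. None of these was tested.

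The second pattern is the 56 genes listed in both 2 mM libraries and at 0 in both 15 mM libraries. Of 1558 genes above 0 in both 2 mM libraries with a mean there of at least 100 FPKM, 38 were at 0 in both 15 mM libraries and 44 in 1 of them (9 and 9 of the 494 genes at 500 FPKM or more), counts that did not decide by the comparison made for the first pattern. A further comparison, made after that one, gave a share at 0 in both of 2.44% (95% Clopper-Pearson interval 1.73% to 3.33%, counting error only). This lay above the 1.27% that one 15 mM library missed of the other at matched levels, although very short genes were not tested. The match used 2 mM levels of genes picked for being above 0 in both 2 mM libraries. Genes above 0 in all 4 libraries had a median of 175 FPKM at 2 mM and 120 FPKM at 15 mM. At lower levels the 15 mM libraries missed more: at 20 to 50 FPKM in one, 92.4% and 94.7% were above 0 in the other. The comparison therefore does not decide, and loss of reads stays open at this level. For the 18 members under 100 FPKM, of 718 such genes with 28 at 0 in 1 library, loss of reads stays open, since their share of 2.51% (1.49% to 3.93%) lay above the 0.587% that both would miss if independent and below the 5.64% missed by one at matched levels. Reads placed differently between near-identical gene copies, a different cell form and a response to nitrate stay open, and none of them was tested.

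The third pattern is the 25 whole-number values, such as 440112 FPKM for HaLaN_17920 in replicate 2 at 15 mM beside 437 FPKM in replicate 1. A lost decimal point is a candidate explanation: after division by 1000, 23 of the 23 values with a replicate above 0 lay within 3-fold of it, with ratios from 0.526 to 2.81. The table held 0 values with exactly 3 decimals where 27.8 would be expected from the 278 values with exactly 4, which argues against a rise of these genes in 1 library. The division changed the summed FPKM of replicate 1 at 15 mM from 40920464 to 1483953.

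A group of 24 identifiers carries a letter t before its number. Of these, 0 and 2 were above 0 in the 2 mM libraries and 18 and 4 in the 15 mM libraries, with a highest value of 101 FPKM in replicate 2 at 2 mM.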
